A study of Caenorhabditis elegans with 9 samples.

How the data were processed

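The samples are intestines dissected from adult wild-type (N2) Caenorhabditis elegans grown from the first larval stage for 4 days at 20 °C in mCeHR2 liquid medium with 2, 20 or 400 µM heme. Each library was made by SMART-seq from the pooled intestines of 3 worms, and there are 3 libraries per heme dose, 9 in all. Nothing in the labels says whether the libraries of a dose came from separate cultures, so p-values measure only the spread between these libraries.

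The deposited table holds raw counts per gene for each library, per the file headers, with whole numbers in every cell. It also holds FPKM values computed by the authors. The length implied by count, FPKM and library total lay within 10% of its median for the gene for 100% of the values compared in 9119 genes. These implied lengths were not set against transcript lengths. The FPKM values entered no comparison. The submitters' processing notes name Bowtie 0.12.2 and the genome build WBcel235. How reads were assigned to genes, and what was done with reads that match several genes, is not stated. Members of families with near-identical sequences, such as the major sperm proteins, can therefore not be separated with certainty.

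The table has 21776 genes, of which 21714 were matched by identifier to the WBcel235 annotation and 1095 carry another symbol there. In the table, hrg-9 stands as R186.1 and hrg-10 as Y80D3A.9. No mitochondrially encoded gene is in the table, so that list had 0 measured genes. The filter filterByExpr kept 13434 genes for testing. Libraries hold 72960600, 62130691 and 54923920 counts at 2 µM heme (replicates 1 to 3), 65555762, 52407256 and 44385011 at 20 µM, and 63132612, 57099679 and 63752331 at 400 µM. Ribosomal RNA took 3.58, 14.1 and 14.8% of the counts at 2 µM, 2.31, 35.5 and 42.1% at 20 µM, and 6.45, 7.73 and 11.5% at 400 µM. The counting error is small beside this spread: the 95% interval of the ribosomal share is at most 0.0145 percentage points wide on each side. A floor of 3 counts corresponds to between 0.0369 and 0.0940 CPM per library.

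Counts were scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) in 1 model with 1 coefficient per heme dose, which lets the 3 groups share the estimate of spread. The biological coefficient of variation was 0.961 and the prior degrees of freedom 2.86. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed in each of 3 pairwise comparisons and in a slope on log10 of the heme dose. CPM values are means of the 3 libraries, given with the SD, and log2 fold changes are given with the SE. Where all libraries of a dose had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Of 39 gene lists, 38 had at least 3 measured genes and were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists. Beside it, camera with an estimated correlation and fry were run, and changed members were counted with adjustment over all genes and over the list alone. The gene lists, comparisons, tests and most alternatives were fixed before the data were examined.

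Genes are named by a rule fixed at the same time. It takes, per comparison, the 8 largest rises and the 8 largest falls among changed genes that have a mean of at least 10 CPM in 1 of the groups and no overlap between the groups' libraries. Where fewer than 3 pass in a direction, the 3 genes with the smallest p are given as values. It adds every measured gene of the heme transport and trafficking list and up to 4 members with the smallest p from each list described. Changed genes outside the rule that are named were chosen after their values were seen. If the libraries are independent, no overlap between 3 and 3 of them occurs in 10% of genes by chance. It occurred in 17.1% of tested genes for 2 against 20 µM, 24.1% for 400 against 20 µM and 28.4% for 2 against 400 µM. Replicates 2 and 3 of 2 µM heme are near-identical, which raises the chance share for the comparisons with 2 µM. The 17.1 and 28.4% can therefore not be read against 10%.

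The alternatives fixed beforehand were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, no filter on low counts, a filter of at least 10 CPM in 3 libraries, only the libraries of the groups compared, a block for the replicate number, and leaving out each library in turn. Added after the data were seen were summing replicates 2 and 3 of 2 µM heme, which are near-identical, removing 18 ribosomal RNA genes, and omitting replicate 1 of 20 µM heme together with that sum. Counts were simulated for independent genes with 1 dispersion per gene for all 9 libraries, and changes were planted in genes of at least 10 CPM. The real spread differs between doses, so the simulated shares and error counts may not hold for these libraries. On the simulated counts, the edgeR test recovered 44.8% of genes changed 16-fold for 2 against 20 µM and 53.7% for 400 against 20 µM. For 64-fold changes these shares were 81.8 and 83.3%, for 4-fold changes 0 and 4.48%, with 2 false calls in each comparison. In the same simulations camera called both planted lists, and 1 of 4 tests of unchanged lists was called in error (adjusted p = 0.0230, and adjusted p = 0.0336 with an estimated correlation). The comparisons with 20 µM share those libraries, so their overlap was set against 20 simulations of unchanged groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.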

Results

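Most genes of heme transport and trafficking, and the list in sum, stood highest in intestines of worms grown with 2 µM heme and lowest at 400 µM. The 12 measured genes of this list together took 1.39 ± 0.158% of all counts at 2 µM, 0.0789 ± 0.0536% at 20 µM and 0.0163 ± 0.00164% at 400 µM (mean ± SD, n = 3 libraries per dose). The most abundant was hrg-7, which encodes a secreted protein that signals heme status between tissues, with 7923 ± 2320 CPM at 2 µM, 634.8 ± 863.5 CPM at 20 µM and 28.6 ± 4.78 CPM at 400 µM. In the same order of doses, hrg-3, a secreted heme chaperone, had 1338 ± 279, 72.1 ± 108 and 3.11 ± 0.923 CPM. The heme importer hrg-1 had 458 ± 78.9, 44.2 ± 62.6 and 2.67 ± 0.935 CPM. The importer hrg-4 had 152 ± 62.3, 18.8 ± 11.6 and 1.89 ± 1.199 CPM. For mrp-5, an ABC transporter that exports heme from the intestine, the means were 1266 ± 468, 332 ± 204 and 68.7 ± 22.2 CPM. For hrg-2, a heme-binding protein, the values were 1309 ± 1107, 1.86 ± 0.993 and 0.809 ± 0.728 CPM. The order does not hold for every member. Mean CPM at 2, 20 and 400 µM was lowest at 20 µM for hrg-9 (26.2, 0.930 and 1.88) and gst-19 (143, 11.04 and 11.4), and highest there for gst-22 (29.9, 35.2 and 19.9), hrg-5 (1.04, 1.60 and 0.898) and hrg-10 (2.18, 2.29 and 2.21). For gst-22, hrg-5 and hrg-10 this rests on 20 µM replicate 1. With it left out, their log2 fold changes for 2 against 20 µM were 0.97, 1.67 and 0.53, and none passed (edgeR adjusted p = 0.409, 0.554 and 0.696). The median log2 fold change of all genes was 0.40 in that fit, against 0.12 with all libraries. The genes named first lie on chromosomes V (hrg-7 at 12742041 to 12744171, hrg-3 at 9756468 to 9757019, hrg-2 at 12409415 to 12410513), X (hrg-1 at 4008058 to 4016250, mrp-5 at 14938502 to 14946317) and IV (hrg-4 at 11030143 to 11030993).

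**Figure D1:**
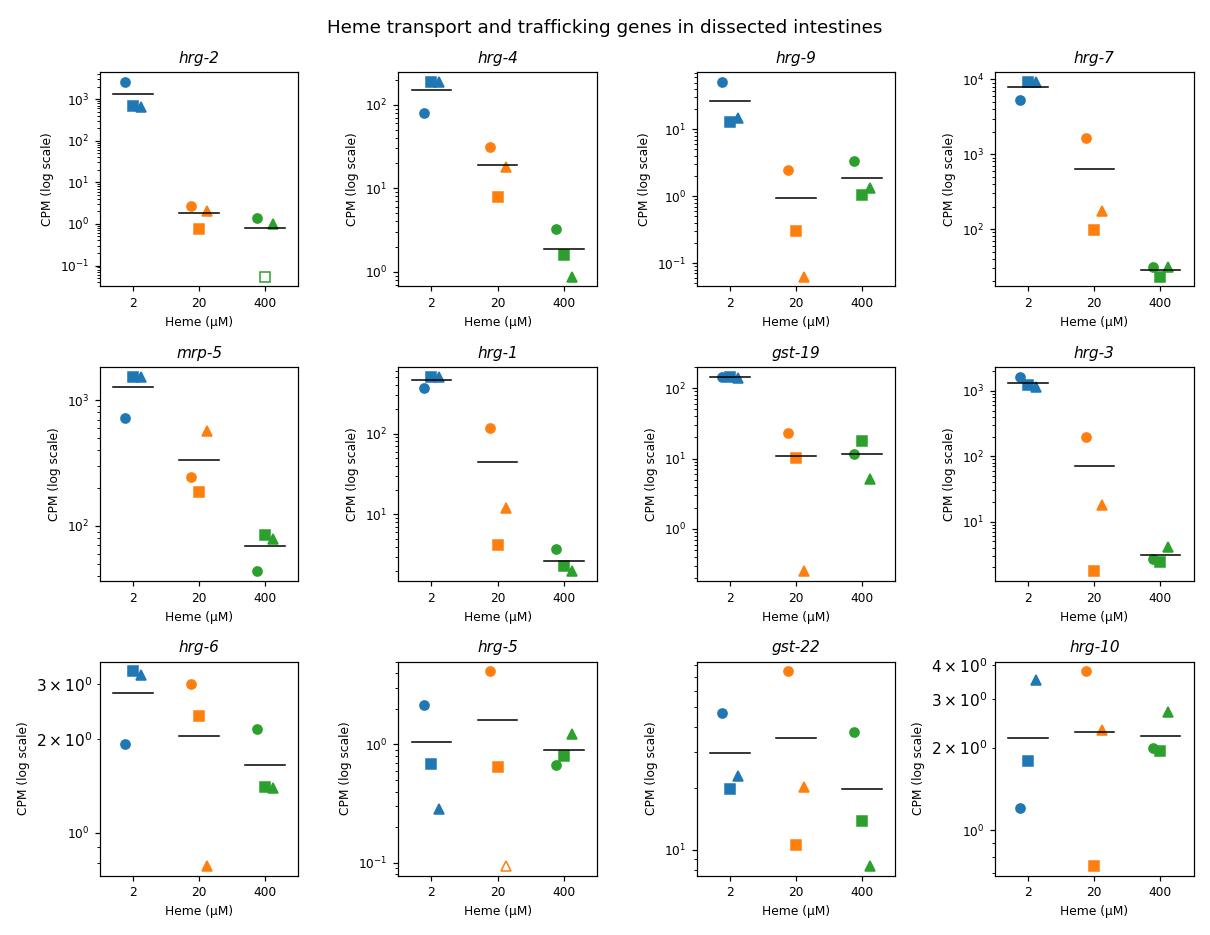
CPM (log axis) against the heme dose in µM for the 12 measured heme transport and trafficking genes, 1 panel per gene. Circles, squares and triangles are replicates 1, 2 and 3, and a black bar at each dose is the group mean. Open symbols stand for 0 counts drawn at a floor of 3 counts. All 3 libraries at 2 µM lie above all 3 at 400 µM for hrg-7, hrg-3, hrg-1, hrg-4, mrp-5 and hrg-2, and 20 µM replicate 1 stands above the other 20 µM libraries for hrg-1, hrg-7 (1631 CPM) and hrg-3 (197 CPM).

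From 20 to 2 µM heme, 8 of the 12 heme genes rose with adjustment over the list alone. By log2 fold change these were hrg-2 (9.46, SE 1.81, adjusted p = 0.00691), hrg-9 (4.81, SE 1.28, adjusted p = 0.0183), a gene of heme trafficking, hrg-4 (3.01, SE 0.71, adjusted p = 0.0130). The others were hrg-3, gst-19, hrg-7, hrg-1 and mrp-5 (4.21, 3.70, 3.64, 3.37 and 1.93, adjusted p = 0.0203 for each). Members that did not pass, hrg-6, gst-22, hrg-10 and hrg-5, had log2 fold changes of 0.45, −0.23, −0.07 and −0.62. Over all genes tested, edgeR called 0 of the 12, although 8 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 6 each. As a list they rose relative to other genes (camera adjusted p = 4.47e-05, median log2 fold change 3.19), with adjusted p = 0.657 with an estimated correlation. In 20 µM replicate 1, hrg-7 stood at 1631 CPM and hrg-3 at 197 CPM, while replicates 2 and 3 had 98.1 and 176 CPM of hrg-7, 1.74 and 17.7 CPM of hrg-3, and 4.22 and 11.9 CPM of hrg-1. Without that library the log2 fold changes were 5.87 for hrg-7, 7.12 for hrg-3, 5.84 for hrg-1, 7.06 for hrg-9 and 4.80 for gst-19, and 4 heme genes passed over all genes. Without 2 µM replicate 1 those of hrg-2 and hrg-9 were 8.503 and 3.91. Without 20 µM replicate 2 that of hrg-3 was 3.61, without 20 µM replicate 3 that of mrp-5 was 2.57. Without 400 µM replicate 2, 1 heme gene passed over all genes. With the 400 µM libraries left out of the fit, 3 of the 12 passed over the list alone.

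Beyond the heme list, 10 of 13434 genes changed between 2 and 20 µM heme, 8 of them higher at 2 µM and 2 lower. Genes that rose include cysl-2, a member of the cysteine synthase family and a target of the hypoxia factor HIF-1 (78.6 ± 8.89 against 1.55 ± 0.115 CPM, log2 fold change 5.66, SE 0.47, adjusted p = 0.0113). So did ugt-16, a glucuronosyltransferase (479 ± 25.1 against 18.5 ± 11.6 CPM, adjusted p = 0.0436), and gln-1, a glutamine synthetase (87.9 ± 6.003 against 7.15 ± 2.01 CPM, adjusted p = 0.0291). Among genes without a common name, F36A2.3 (206 against 0.636 CPM, adjusted p = 0.0368), ZK154.1 (99.5 against 0.552 CPM, adjusted p = 0.0368) and C24D10.5 (69.0 against 0.374 CPM, adjusted p = 0.0265) rose. W03D8.9 and tbh-1, a tyramine beta-hydroxylase, had 0 counts at 20 µM and were at least 274-fold and 89.4-fold higher at 2 µM, at 6.17 and 2.01 CPM. With 20 µM replicate 2 omitted these bounds were 146-fold and 47.8-fold. The genes that fell were pud-4 (0.468 against 734 CPM, log2 fold change −10.61, SE 1.36, adjusted p = 0.0442) and F43G6.17 (0.141 against 6.65 CPM, adjusted p = 0.0368). W03D8.9, tbh-1 and F43G6.17 lie outside the naming rule or its CPM minimum. The third-ranked fall by p, comt-4, of the catechol-O-methyltransferase family, had 0.0357 against 9.37 CPM and adjusted p = 0.0580. Without 20 µM replicate 1 the log2 fold changes were 9.35 for F36A2.3, 8.45 for C24D10.5, 5.31 for ugt-16 and −9.91 for pud-4, and without 20 µM replicate 2 that of ZK154.1 was 8.43. In the first of these fits comt-4 passed (log2 fold change −7.32, adjusted p = 0.0352), and in the second ZK154.1 did not (adjusted p = 0.0678). An unadjusted p under 0.05 was reached by 1804 genes, where chance gives 671.7 if the libraries are independent. DESeq2 counted 1018 changed genes (651 higher at 2 µM and 367 lower) and limma-voom 253 (91 higher and 162 lower). The edgeR count was 210 without 20 µM replicate 1, 0 without 20 µM replicate 2 and 5 without replicate 3. It was 3, 0 and 0 without 2 µM replicates 1, 2 and 3, and 4 and 1 without 400 µM replicates 1 and 3. With a block for the replicate number it was 2, 1 of them among the 10. With only the libraries of the groups compared it was 0 (1035 at an unadjusted p under 0.05). Replicates 2 and 3 of 2 µM heme are near-identical (Pearson r across genes 0.976, against 0.740 to 0.913 for the 8 other pairs within a dose). With their counts summed, 0 genes passed in edgeR, with 1341 at an unadjusted p under 0.05.

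Of the 38 lists, 9 were called between 2 and 20 µM heme, 4 higher and 5 lower at 2 µM. Sperm markers rose, 26 of 73 over the list alone (camera adjusted p = 3.91e-14, median log2 fold change 2.39, adjusted p = 0.672 with an estimated correlation). Examples are the major sperm protein genes msp-55 (46.2 ± 2.21 against 3.39 ± 0.618 CPM) and msp-51 (67.4 ± 14.7 against 4.98 ± 1.32 CPM). Pharynx markers fell, 12 of 13 over the list alone (camera adjusted p = 1.55e-08, adjusted p = 0.657 with an estimated correlation). They include the pharyngeal myosins myo-1 (0.981 against 43.8 CPM) and myo-2 (2.41 against 84.4 CPM), and phat-2, with 0 counts at 2 µM and 3.11, 188 and 2.73 CPM in 20 µM replicates 1, 2 and 3. The pharynx list took 0.0439, 0.185 and 0.00233% of the counts in 20 µM replicates 1, 2 and 3 and between 0.00144 and 0.00172% at 2 µM. Its level at 20 µM thus comes mostly from replicates 1 and 2. The pharynx and sperm lists were included to describe tissue other than intestine in the dissected samples. The fall of the first and the rise of the second need not be changes in the intestine. The log2 fold change of myo-1 was −5.48, and −4.88 without 20 µM replicate 1, and that of myo-2 was −5.13, and −4.33 without 20 µM replicate 2. Smaller shifts were called for the nuclear-encoded respiratory chain and the vacuolar ATPase, higher at 2 µM (median log2 fold change 0.55 and 0.59, camera adjusted p = 0.00582 and 0.0238, adjusted p = 0.80 for each with an estimated correlation). Lists that fell were fatty acid oxidation (camera adjusted p = 0.00184), lysozymes and saposin-like proteins (0.00232), pathogen response genes (0.00624) and cytosolic ribosomal proteins (1.28e-05). Their medians were −0.48, −0.59, −1.13 and −0.28, and adjusted p = 0.657, 0.657, 0.672 and 0.80 with an estimated correlation. In these 6 smaller lists 1 member passed over the list alone, the lysozyme ilys-4 (1.48 against 13.1 CPM, log2 fold change −3.14, and −2.51 without 20 µM replicate 3). As a share of all counts, ribosomal proteins took 10.5 ± 2.36% at 2 µM and 10.1 ± 4.59% at 20 µM. All counts include ribosomal RNA, which took 35.5 and 42.1% in 20 µM replicates 2 and 3 and lowers other shares there. These sums therefore do not tell the direction. Calls were lost without 2 µM replicate 1 for ribosomal proteins (adjusted p = 0.442), without 20 µM replicate 1 for lysozymes (0.0983). They were lost without 20 µM replicate 3 for the pathogen response (0.334), the respiratory chain (0.0872) and the vacuolar ATPase (0.219). The latter 2 were also lost without 2 µM replicate 2 (0.0589 and 0.0852) or 3 (0.0857 for both), and the vacuolar ATPase without 20 µM replicate 2 (0.153). Without 2 µM replicate 1, 14 lists were called.

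Between 400 and 20 µM heme, sperm transcripts stood higher at 400 µM. Of 73 measured sperm markers 51 rose over the list alone and 12 over all genes (camera adjusted p = 3.75e-24, median log2 fold change 4.68, or 4.61 with genes at 0 set to their bound). For this list adjusted p = 0.555 with an estimated correlation, and fry adjusted p = 0.0198. The gene msp-59 had 632 ± 485 CPM at 400 µM and 10.4 ± 4.90 CPM at 20 µM (log2 fold change 5.93, SE 0.85, adjusted p = 0.0355). Also called, msp-51 had 421 ± 326 and 4.98 ± 1.32 CPM, and ssp-11 had 277 ± 216 and 4.93 ± 2.41 CPM. Sperm markers took 1.57, 0.147 and 0.885% of the counts in 400 µM replicates 1, 2 and 3, 0.0153, 0.0138 and 0.0325% at 20 µM, and 0.163, 0.159 and 0.157% at 2 µM. Germline and oocyte markers rose too, 13 of 28 over the list alone and 0 over all genes in edgeR (camera adjusted p = 1.58e-09, adjusted p = 0.648 with an estimated correlation). Examples are the eggshell genes perm-2 (536 ± 444 against 2.58 ± 2.22 CPM) and perm-4 (485 ± 355 against 4.30 ± 4.07 CPM). The P granule genes passed as well: glh-1 (32 ± 5.16 against 11.3 ± 2.90 CPM) and pgl-3 (17.99 ± 7.11 against 3.63 ± 1.59 CPM). Without 400 µM replicate 1 the log2 fold changes of msp-51, msp-59 and ssp-11 were 5.78, 5.27 and 5.16. Those of perm-2 and perm-4, 7.70 and 6.82 with all libraries, were 6.81 and 6.13 without 400 µM replicate 2. That of perm-2 was 8.30 without 20 µM replicate 1, where it passed over all genes (adjusted p = 0.0445), and that of perm-4 was 7.76 without 20 µM replicate 3.

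**Figure D2:**
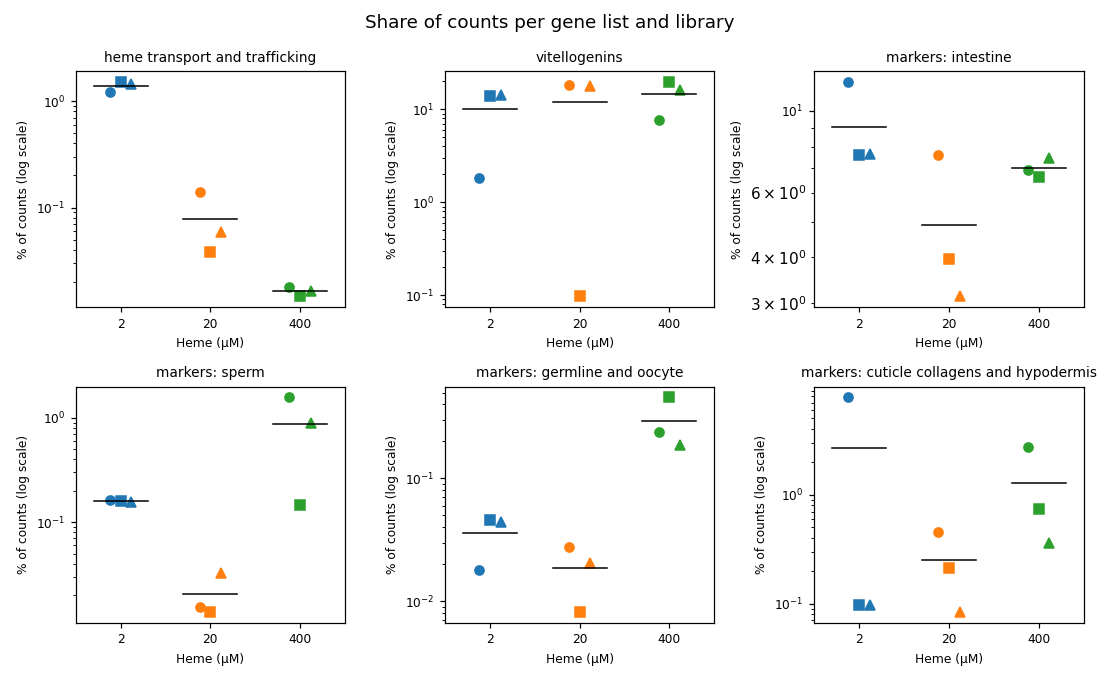
Percent of all counts (log axis) taken by 6 gene lists against the heme dose in µM. Circles, squares and triangles are replicates 1, 2 and 3, and a black bar at each dose is the group mean. The heme list lies between 1.21 and 1.51% in the 2 µM libraries and between 0.0146 and 0.0179% in the 400 µM libraries, sperm markers between 0.147 and 1.57% at 400 µM and between 0.0138 and 0.0325% at 20 µM.

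In all, 74 genes changed between 400 and 20 µM heme, 73 of them higher at 400 µM. They include 9 major sperm protein genes and 3 ssp genes of the sperm list, and 5 genes of the nematode-specific peptide families (nsp), which are not in that list. Members of such families are alike in sequence, so that reads may not be separated between them. A dissected intestine may hold gonad, and the lists do not show which of the other changed genes are expressed there. For these genes too, carried-over gonad can therefore not be told apart from an effect of heme. The largest rises that pass the naming rule had 0 counts at 20 µM: W03D8.9 was at least 1189-fold higher at 400 µM (26.8 ± 15.7 CPM), C17H12.3 at least 657-fold (14.8 ± 16.43 CPM) and tbh-1 at least 644-fold (14.5 ± 4.37 CPM). The others were ZK637.12 at least 534-fold, C24A11.1 at least 514-fold, C06A1.3 at least 502-fold and C01G12.3 at least 458-fold. With 20 µM replicate 2 omitted, which leaves fewer counts to set the bound, these were 635-fold for W03D8.9, 344-fold for tbh-1, 351-fold for C17H12.3, 285-fold for ZK637.12, 275-fold for C24A11.1, 268-fold for C06A1.3 and 244-fold for C01G12.3. W09C3.7 had 31.5 ± 19.1 CPM at 400 µM and 4 counts over the group at 20 µM. Omitting 400 µM replicate 1 took the lower bounds of C17H12.3, ZK637.12, C24A11.1 and C06A1.3 to 241-fold, 257-fold, 218-fold and 206-fold, and none of these 4 passed (adjusted p = 0.104, 0.104, 0.104 and 0.124). All 4 counts of W09C3.7 at 20 µM lie in replicate 2, and with it omitted the gene was at least 747-fold higher at 400 µM and did not pass (adjusted p = 0.0694). The 1 gene that fell was R07B7.6 (5.13 ± 1.55 against 24.9 ± 3.81 CPM, log2 fold change −2.28, SE 0.37, adjusted p = 0.0403). Next by p were amph-1 (8.73 against 37.3 CPM, adjusted p = 0.0604) and C08E8.4 (2.1 against 21.9 CPM, adjusted p = 0.0605), which did not pass. For C08E8.4 the 20 µM replicates stood at 9.70, 44.8 and 11.1 CPM, and omitting replicate 2 moved the log2 fold change from −3.38 to −2.28. An unadjusted p under 0.05 was reached by 2486 genes. DESeq2 counted 1722 changed genes (1282 higher at 400 µM and 440 lower) and limma-voom 0, with 1912 at an unadjusted p under 0.05, and edgeR with a block for the replicate number counted 0. Leaving out 20 µM replicate 1, 2 or 3 gave 953, 1 and 1 genes, and leaving out 400 µM replicate 1, 2 or 3 gave 0, 135 and 0. Leaving out any of the 3 libraries at 2 µM, or summing its replicates 2 and 3, gave 0. Fitting only the libraries of the groups compared also gave 0 (1756 at an unadjusted p under 0.05).

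From 20 to 400 µM heme, 5 heme genes fell with adjustment over the list alone. These were hrg-3, hrg-7, hrg-1, hrg-4 and mrp-5, with log2 fold changes of −4.53, −4.47, −4.05, −3.31 and −2.27 and adjusted p = 0.0244, 0.0171, 0.0179, 0.0155 and 0.0171. Over all genes 0 fell in edgeR (5 at an unadjusted p under 0.05), 3 in DESeq2 and 0 in limma-voom. The list as a whole fell (camera adjusted p = 0.0124, median −1.01, adjusted p = 0.674 with an estimated correlation). Without 20 µM replicate 1 the list was not called (adjusted p = 0.227), 1 heme gene passed over all genes, and 1 rose over the list alone. The log2 fold changes of hrg-3, hrg-7 and hrg-1 without it were −1.63, −2.25 and −1.59. Without 20 µM replicate 3 that of mrp-5 was −1.64, and without 400 µM replicate 1 that of hrg-4 was −3.90. Leaving out 400 µM replicate 1, 2 or 3 left 1, 0 and 0 falls over the list alone, and the block left 3.

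Of the 38 lists, 13 were called between 400 and 20 µM, 2 higher at 400 µM (sperm and germline) and 11 lower. Beside the heme list, those lower were cytochrome P450 genes (2 of 57 over the list alone, cyp-33E2 at 4.40 against 24.1 CPM and cyp-33C9 at 7.56 against 22.2 CPM), nuclear hormone receptors, pathogen response genes and cytosolic ribosomal proteins. Camera adjusted p = 3.08e-05, 1.00e-07, 0.000453 and 1.86e-08 in that order, with medians of −1.105, −0.58, −1.33 and −0.57, and adjusted p = 0.555, 0.555, 0.555 and 0.807 with an estimated correlation. Pharynx markers, again high in 20 µM replicates 1 and 2, were lower at 400 µM (camera adjusted p = 0.000310, adjusted p = 0.669 with an estimated correlation). By the ranking of genes, ABC transporters, fatty acid oxidation, intestine markers, collagens with hypodermis genes and glucuronosyltransferases were also called lower (camera adjusted p = 0.0113, 0.0216, 0.0216, 0.0282 and 0.0364, medians −0.67, −0.51, −0.61, −2.41 and −0.62). For these adjusted p = 0.669, 0.555, 0.669, 0.941 and 0.857 with an estimated correlation, and 0 members passed over the list alone in edgeR. The mean summed share was higher at 400 µM for intestine markers (6.99 ± 0.437% against 4.89 ± 2.36% at 20 µM) and collagens with hypodermis genes (1.28 ± 1.28 against 0.250 ± 0.188%). Intestine markers took 7.57, 3.96 and 3.13% in 20 µM replicates 1, 2 and 3. In 400 µM replicates 1, 2 and 3 they took 6.90, 6.60 and 7.46%. Fatty acid oxidation took 0.387 and 0.372% of all counts. For intestine markers and fatty acid oxidation the sums do not tell the direction, since ribosomal RNA lowers the shares in 20 µM replicates 2 and 3. The mean log2 fold change of ABC transporters was 0.01. By fry, globin family genes also moved, upward (adjusted p = 0.0198), a list camera did not call (adjusted p = 0.253). Without 20 µM replicate 1 the calls of glucuronosyltransferases (adjusted p = 0.210), fatty acid oxidation (0.0828), intestine (0.375) and collagens (0.274) were lost. Glucuronosyltransferases (0.128) and ABC transporters (0.0696) were lost without 20 µM replicate 2, and fatty acid oxidation was lost without 20 µM replicate 3 (0.0619) or 400 µM replicate 1 (0.135). Without 400 µM replicate 2 or 3, glucuronosyltransferases (0.0803) and collagens (0.0990) were lost.

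The widest contrast, 2 against 400 µM heme, had 14 changed genes, 11 higher at 2 µM and 3 lower. Those that rose include gsto-1, an omega-class glutathione transferase (1329 ± 367 against 13.6 ± 4.35 CPM, log2 fold change 6.61, SE 0.74, adjusted p = 0.0294), and hrg-4 (log2 fold change 6.32, SE 0.82, adjusted p = 0.0451). Others are cysl-2 (78.6 ± 8.89 against 1.43 ± 0.561 CPM, adjusted p = 0.00995), ugt-16 (479 ± 25.1 against 12.56 ± 3.24 CPM, adjusted p = 0.0295) and cdr-4, a cadmium-responsive gene (190 ± 7.87 against 13.4 ± 4.51 CPM, adjusted p = 0.0479). ZK154.1 (99.5 against 0.0656 CPM), C24D10.5 (69.0 against 1.64 CPM) and C02D5.4 (1129 ± 475 against 41.3 ± 12.04 CPM) rose as well. Outside the 8 largest, gln-1 (87.9 against 6.98 CPM), D1007.15 (127 against 9.64 CPM) and the cytochrome P450 gene cyp-33C9 (71.3 ± 14.8 against 7.56 ± 1.36 CPM), named after their values were seen, complete the rises. The falls were comt-4 (0.0357 against 57.8 CPM, log2 fold change −10.54, SE 1.25, adjusted p = 0.0316), pud-4 (0.468 against 345 CPM, log2 fold change −9.52, SE 1.31, adjusted p = 0.0481) and F43G6.17 (0.141 against 3.63 CPM, adjusted p = 0.0481). In the heme list 8 of 12 genes rose over the list alone and 1, hrg-4, over all genes, or 0 with the replicate block. Log2 fold changes were 10.65 for hrg-2, 8.75 for hrg-3, 8.11 for hrg-7, 7.42 for hrg-1, 4.20 for mrp-5, 3.79 for hrg-9 and 3.65 for gst-19. As a list they rose (camera adjusted p = 4.26e-11, median 4.00, adjusted p = 0.342 with an estimated correlation, fry adjusted p = 0.0383). Without 2 µM replicate 1 the log2 fold changes of hrg-2 and hrg-9 were 9.62 and 2.82. Without 20 µM replicate 1 or 3, 5 and 3 heme genes passed over all genes, and leaving out 20 µM replicate 2 or any library of 2 or 400 µM left 0. An unadjusted p under 0.05 was reached by 1419 genes. DESeq2 counted 612 changed genes and limma-voom 3670, with more falls than rises at 2 µM in both (239 higher and 373 lower, and 1295 higher and 2375 lower). The edgeR count was 284 with only the 6 libraries compared and 4 with the replicate block. Without 2 µM replicates 1, 2 and 3 in turn it was 2, 0 and 0, and without those of 20 µM it was 54, 5 and 53. It was 0 without any of the 400 µM libraries, and 0 with 2 µM replicates 2 and 3 summed (979 at an unadjusted p under 0.05).

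Detoxification families were among the 18 lists called between 2 and 400 µM, 15 higher at 2 µM and 3 lower. Glucuronosyltransferase genes rose (14 of 54 up and 1 down over the list alone, camera adjusted p = 0.000117, adjusted p = 0.681 with an estimated correlation). Examples are ugt-12 (417 ± 265 against 5.62 ± 2.98 CPM), ugt-21 (149 ± 59.5 against 5.04 ± 1.54 CPM) and ugt-17 (159 ± 14.6 against 21.4 ± 6.48 CPM). Cytochrome P450 genes were called higher as a list (7 of 57 over the list alone, camera adjusted p = 0.00330, adjusted p = 0.681 with an estimated correlation). Among them cyp-14A4 stood at 38.8 ± 4.13 CPM at 2 µM and 0 counts at 400 µM, at least 2722-fold higher at 2 µM (1706-fold without 400 µM replicate 1 and 1733-fold without replicate 3), and cyp-35A2 at 382 ± 75.2 against 40.4 ± 2.49 CPM. Glutathione transferases ranked higher as a list (camera adjusted p = 0.000247, adjusted p = 0.712 with an estimated correlation), with 1 of 36 over the list alone and 7 at an unadjusted p under 0.05. Their summed counts took 0.423, 0.185 and 0.177% in the 2 µM replicates and 0.188, 0.132 and 0.110% at 400 µM. Metal detoxification genes also ranked higher (2 of 15, cdr-4 and cdr-2, camera adjusted p = 0.000616, adjusted p = 0.567 with an estimated correlation). Their summed counts took 0.573, 0.199 and 0.194% in the 2 µM replicates and 0.222, 0.192 and 0.242% at 400 µM. Genes of the hypoxia and hydrogen sulfide response rose as a list (camera adjusted p = 0.000559, adjusted p = 0.349 with an estimated correlation), with cysl-2 the 1 member of 12 that passed. Nuclear hormone receptors ranked higher as a list, with 4 of 175 over the list alone, 0 over all genes in edgeR and 21 at an unadjusted p under 0.05 (camera adjusted p = 2.65e-07, adjusted p = 0.465 with an estimated correlation). The mitochondrial and endoplasmic reticulum unfolded protein responses and oxidative stress genes were called higher with 0 members passing over the list alone in edgeR (camera adjusted p = 0.000792, 0.000616 and 0.0225, adjusted p = 0.342, 0.465 and 0.712 with an estimated correlation). The log2 fold change of ugt-12 was 6.21, and 5.50 without 2 µM replicate 1. Without that library the P450 call was lost (adjusted p = 0.0932), and without 400 µM replicate 1 that of oxidative stress (0.0600).

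Germline and oocyte markers were lower at 2 than at 400 µM, 15 of 28 over the list alone (camera adjusted p = 5.93e-13, median −2.52, adjusted p = 0.465 with an estimated correlation). Examples are glh-1 (7.06 ± 1.23 against 32 ± 5.16 CPM) and pgl-3 (3.36 ± 0.859 against 17.99 ± 7.11 CPM). Sperm markers were lower as a list (camera adjusted p = 4.26e-11, median −2.197, adjusted p = 0.621 with an estimated correlation). Their summed share was 1.57, 0.147 and 0.885% in 400 µM replicates 1, 2 and 3, and 0.163, 0.159 and 0.157% in those of 2 µM. Replicate 2 of 400 µM thus lay below the 2 µM libraries. In edgeR 0 of 73 passed over the list alone and 29 at an unadjusted p under 0.05. Collagens and hypodermis genes were called higher at 2 µM (camera adjusted p = 0.0308, adjusted p = 0.761 with an estimated correlation). They took 7.81% of the counts in 2 µM replicate 1 and 0.0981 and 0.0960% in replicates 2 and 3, and without replicate 1 the direction turned (adjusted p = 0.0215). The collagen call was also lost without 20 µM replicate 1 (0.0553) or 400 µM replicate 3 (0.0844). Cathepsins, the vacuolar ATPase, ribosomal proteins and intestine markers were called higher and lipases lower (camera adjusted p = 0.0342, 0.0308, 0.0279, 0.0342 and 0.0441, adjusted p = 0.712, 0.761, 0.761, 0.681 and 0.712 with an estimated correlation). Each of these calls was lost without 2 µM replicate 2 (adjusted p = 0.0582, 0.0855, 0.442, 0.0766 and 0.388, in the order above) and without 2 µM replicate 3 (0.0538, 0.114, 0.853, 0.114 and 0.468). Cathepsins, ribosomal proteins, intestine and lipases were lost without 400 µM replicate 1 (0.0546, 0.693, 0.0546 and 0.173). Cathepsins, the vacuolar ATPase, intestine and lipases were lost without 400 µM replicate 3 (0.1004, 0.107, 0.0602 and 0.171), and lipases without 400 µM replicate 2 (0.220). Omitting 20 µM replicate 2 ended the calls of cathepsins, the vacuolar ATPase, ribosomal proteins and intestine (0.0513 for each). Omitting 20 µM replicate 1 or 3 ended that of lipases (0.0741 and 0.208), and omitting 2 µM replicate 1 that of cathepsins (0.108).

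Over the whole dose range, 10 genes fell with rising heme and 0 rose in edgeR (1144 at an unadjusted p under 0.05, 631 of them falling). DESeq2 counted 377 genes, 172 rising and 205 falling, and limma-voom 3383, of which more rose (2025) than fell (1358). Per 10-fold of heme, log2 expression fell by 3.52 for hrg-7 (SE 0.49, adjusted p = 0.0493), by 2.74 for hrg-4 (SE 0.32, adjusted p = 0.0216), and by 2.84 for gsto-1 (SE 0.33, adjusted p = 0.0216). It fell by 1.65 for cdr-4 (SE 0.21, adjusted p = 0.0365) and by 1.40 for cyp-33C9 (SE 0.16, adjusted p = 0.0216). The others are ZK154.1, cyp-14A4, F07C4.10, acr-19 and R193.2, the last 3 named after their values were seen. Without 2 µM replicates 1, 2 and 3 the count was 4, 0 and 0, and without 20 µM replicate 3 it was 24. Without any 400 µM library it was 0, and with 2 µM replicates 2 and 3 summed 0 (1040 at an unadjusted p under 0.05).

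Both 2 and 400 µM were compared with the same 20 µM libraries, and 2 genes changed in the same direction in both, tbh-1 and W03D8.9, with 0 counts at 20 µM. Independent lists of these sizes would share 0.0435 rises. Across genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson r of 0.68, against 0.51 (0.49 to 0.53) in simulations of unchanged groups that share the 20 µM libraries. Their covariance was 4.73, against 1.05 in the simulations, a difference of 3.68. With 3 libraries the 20 µM group cannot be divided to give each comparison its own controls. Its spread enters both comparisons, and it was wide, with a biological coefficient of variation of 1.08 to 1.23 between pairs, against 0.576 to 0.767 at 400 µM. A wider spread at 20 µM than simulated would also raise the covariance, so the difference does not show a shared response. The shared count was 129 without 20 µM replicate 1, 4 without 400 µM replicate 2, 1 without 20 µM replicate 3 and 0 without any other library.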

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

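Summing 2 µM replicates 2 and 3, removing the ribosomal RNA genes, and omitting 20 µM replicate 1 together with that sum were chosen after the results were seen, and every other alternative was fixed beforehand. Counts of changed genes are given for 2 against 20 µM, 400 against 20 µM, 2 against 400 µM and the trend, in that order, where edgeR gave 10, 74, 14 and 10. DESeq2 gave 1018, 1722, 612 and 377. Limma-voom gave 253, 0, 3670 and 3383 (1912 at an unadjusted p under 0.05 where it gave 0). With no low-count filter the counts were 18, 147, 29 and 14, with at least 10 CPM in 3 libraries 26, 42, 60 and 24, and with the replicate block 2, 0, 4 and 3. With only the libraries of the groups compared, edgeR gave 0, 0 and 284 (1035 and 1756 at an unadjusted p under 0.05 where it gave 0). With 2 µM replicates 2 and 3 summed it gave 0, 0, 0 and 0 (1341, 2157, 979 and 1040 at an unadjusted p under 0.05), and with 20 µM replicate 1 omitted as well 2, 0 and 15 for the pairwise comparisons (3574 at an unadjusted p under 0.05 where it gave 0). DESeq2 size factors (9, 73, 14 and 7) and removal of ribosomal RNA genes (13, 75, 14 and 8) stayed within 1.5 times. The median log2 fold change of all genes for 2 against 400 µM was 0.02 with TMM and −0.10 with DESeq2 size factors. Leaving out each library gave 0 to 210, 0 to 953, 0 to 54 and 0 to 24 genes. For 2 against 20 µM, leaving out 2 µM replicates 1, 2 and 3 gave 3, 0 and 0, 20 µM replicates 1, 2 and 3 gave 210, 0 and 5, and 400 µM replicates 1, 2 and 3 gave 4, 10 and 1. The overlap of 2 genes was 0 with the block and 0 to 129 when leaving out each library (129 without 20 µM replicate 1, 4 without 400 µM replicate 2, 1 without 20 µM replicate 3, 0 otherwise). Of the 9, 13 and 18 lists called by camera, 0, 0 and 0 were called with an estimated correlation and 0, 2 and 1 by fry, for which the smallest adjusted p in the first comparison was 0.0753. With the block 9, 11 and 20 lists were called, with the sum 7, 13 and 13, and leaving out each library gave 7 to 14 (14 without 2 µM replicate 1), 10 to 15 and 13 to 19. Whether replicate numbers pair the libraries is not settled by the labels. Residual correlations between libraries of the same number ran from 0.17 to 0.21 for replicate 1, from −0.11 to 0.02 for replicate 2 and from 0.21 to 0.26 for replicate 3, against −0.28 to 0.25 for other pairs, and 6 of 9 libraries were closest to one of their own number. Alternatives for normalized values (pseudocounts and value filters) were not run, since the table holds counts, and a trend was not fitted with the groups compared alone. The cause of these differences was not tested.

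For named genes, 1110 values over the alternatives kept their direction and side of the threshold for 2 against 20 µM, 1275 for 400 against 20 µM and 1511 for 2 against 400 µM. There 106, 156 and 124 lost the call, 54, 59 and 179 gained it and 21, 39 and 10 turned direction. Only genes called in the main fit can lose the call, and most named genes were not called there. The values that were kept are therefore mostly of uncalled genes and do not measure how stable the calls are. For 2 against 20 µM, cysl-2 lost the call in 6 of 19 alternatives, gln-1 in 11 of 19 and F43G6.17 in 12 of 18. None of the 8 heme genes that rose over the list alone at 2 µM turned direction in that comparison. Those that turned had log2 fold changes as follows. For 2 against 20 µM, with the block: hrg-10 0.011 and gst-22 0.11. With limma-voom: hrg-10 0.65, hrg-5 0.13, vit-2 2.11, vit-3 2.55, vit-4 3.20 and vit-5 1.92. With 20 µM replicate 1 omitted and the sum: hrg-10 0.35, gst-22 1.16, hrg-5 2.03, vit-3 1.67 and vit-4 3.20. For 400 against 20 µM, hrg-10 was 0.00056 with DESeq2 and 0.027 without the filter. With the block: hrg-10 0.081, vit-3 0.068, hrg-5 0.80, vit-4 0.69 and ftn-1 0.083. With limma-voom: hrg-10 0.57, vit-2 2.1, vit-3 3.24, hrg-5 1.09 and vit-4 3.88. With 20 µM replicate 1 omitted and the sum: hrg-10 0.53, hrg-6 0.070, nhr-57 0.29, vit-3 3.17, gst-22 0.37, hrg-5 1.46, vit-4 4.73, ftn-2 1.02 and ftn-1 0.64. For 2 against 400 µM, hrg-5 was −0.82 with the block and −0.96 with limma-voom, and hrg-10 was 0.020 with the groups compared alone and 0.075 with limma-voom. Leaving out each library gave these ranges for 2 against 20 µM: hrg-10 −0.64 to 0.53, hrg-5 −1.69 to 1.67, gst-22 −0.72 to 0.97, vit-2 −1.64 to −0.37, vit-3 −2.47 to 2.05, vit-4 −2.70 to 3.59 and vit-5 −2.66 to 0.077. For 400 against 20 µM: ftn-1 −1.98 to 0.64, ftn-2 −1.68 to 1.02, gst-19 −0.52 to 1.15, gst-22 −1.63 to 0.39, hrg-10 −0.43 to 0.54, hrg-5 −1.40 to 1.46, hrg-6 −0.69 to 0.072, nhr-57 −1.11 to 0.29, vit-1 −0.39 to 2.57, vit-2 −1.23 to −0.02, vit-3 −1.32 to 3.18 and vit-4 −1.62 to 4.74. For 2 against 400 µM: hrg-10 −0.64 to 0.22, hrg-5 −0.93 to 0.52 and vit-1 −0.92 to 0.13. Collagens and hypodermis genes, higher at 2 than at 400 µM, were lower without 2 µM replicate 1 (camera adjusted p = 0.0215). Over all libraries left out in turn, the adjusted p of this list ran from 2.35e-08 to 0.0844. The cause of these turns was not tested.

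Depth alone does not account for the low number of genes in 20 µM replicate 3: after thinning all libraries to the same number of counts outside ribosomal RNA, it still had 10947 genes with counts and the other libraries 12840 to 15288. Changes of 4-fold were rarely detected with this spread, with 0 and 4.48% of them recovered in simulated data.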

Other observations

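Vitellogenins, the yolk proteins made by the intestine, took 1.84, 13.9 and 14.4% of the counts in 2 µM replicates 1, 2 and 3, 18.2, 0.0969 and 18.1% at 20 µM, and 7.60, 19.8 and 16.16% at 400 µM, a spread within doses wider than any difference between them. Heat shock genes took 1.77% in 2 µM replicate 1 and 2.57% in 20 µM replicate 1, and at most 0.395% in the other libraries. Body wall muscle markers were highest in 2 µM replicate 1 (0.436%) and 400 µM replicate 1 (0.395%). At 20 µM replicate 1 was the highest too (0.124%). At 2, 20 and 400 µM, replicate 1 also had the highest share of collagens and hypodermis genes (7.81, 0.454 and 2.74%). Its ribosomal RNA share was the lowest at each dose (3.58, 2.31 and 6.45%). Sperm markers and vitellogenins did not follow the replicate number in this way. Whether replicate 1 was a batch was not tested. In the iron handling list, fpn-1.2, a ferroportin, fell with adjustment over the list alone, with 23.7 ± 6.75 CPM at 2 µM against 167 ± 74.0 CPM at 20 µM (log2 fold change −2.81, adjusted p = 0.00391 over the list alone and 0.0971 over all genes in edgeR).

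Other splits of the libraries and the test of low detection were set beforehand, while the tests of the near-identical libraries, of carried-over gonad and of 20 µM replicate 1 were chosen only after the results were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real splits gave 10, 74 and 14 changed genes for 2 against 20, 400 against 20 and 2 against 400 µM, and the highest other split gave 0 in each, so 1, 1 and 1 of the 10 splits gave as many. For lists called, the real splits gave 9, 13 and 18 and the highest other splits 13, 20 and 14, with 6, 6 and 1 of the 10 giving as many. For the trend, 3 of 100 assignments of the 9 libraries to the doses gave at least 10 genes, and the highest other gave 37. The assignment with 37 genes keeps the 2 µM libraries together as an end group, but draws 29 and 84 do so too and gave 0 and 2 genes, and draw 77, with 14 genes, spreads them over all doses, so the structure of the samples that such a count points to is not told by these. For the overlap of 2 genes, 1 of 100 assignments gave as many, the highest other giving 0. Both shares are under 0.05, but they take the 9 libraries as exchangeable, which the near-identical 2 µM replicates 2 and 3 put in doubt. With these summed, no gene passed in either comparison with 20 µM or in the trend, so chance is not excluded for the overlap or the trend.

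Replicates 2 and 3 of 2 µM heme are closer than any other pair, with a biological coefficient of variation of 0.154 against 0.576 to 1.23 for the other pairs within a dose. A single library sequenced again would leave only counting error, a mean chi-square per gene near 1, and the observed value for genes of 20 to 100 counts was 5.75, which argues against it. The chi-square rose 1.297-fold from these genes to those of 500 to 5000 counts, against 5.94 to 19.3-fold in other pairs, which is what 1 pool of RNA or cDNA split before amplification may give. Separate pools of worms that happened to be alike stay open, and no biological explanation was tested. If 1 pool was split, the 2 libraries are not separate replicates and n = 3 overstates the replication at 2 µM. SDs, SEs and p-values that use both libraries may then be too small.

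Sperm transcripts were higher at 400 than at 20 µM heme, and a dissected intestine need not be free of gonad. Low detection at 20 µM that acts alike on genes of the same mean expression over all libraries is argued against. The highest median log2 fold change among 10000 random lists matched on that mean was 0.59, and the sperm list had 4.68. Random lists hold unrelated genes, whose median varies less than that of genes that move together. Carry-over of gonad of a fixed makeup would give similar ratios of sperm to germline counts in all libraries. The ratio was 6.63, 0.322 and 4.71 in the 400 µM replicates in order, a 20.6-fold range. The width of this range rests on 400 µM replicate 2 alone, so it cannot decide whether gonad of a fixed makeup was carried over. Carry-over of separate parts of the gonad could give sperm shares that vary 10.7-fold between the 400 µM libraries, and it cannot be told apart from an effect of heme on the gonad because nothing in the labels records what each dissection held. Of 79 listed sperm genes 0 are in another list and 16 reached 10 CPM in a 20 µM library, and the most abundant, msp-59, msp-57 and msp-40, had 632, 537 and 488 CPM at 400 µM, 10.4, 21.6 and 15.4 at 20 µM, and 106, 117 and 97.1 at 2 µM.

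In 20 µM replicate 1 the genes hrg-7, hrg-3 and hrg-1 stood above the other 20 µM libraries. So did the other measured heme genes except mrp-5. A 2 µM library under a 20 µM label is argued against, since the 12 heme genes stood there at a median share of 0.205 of their 2 µM mean. The share was 0.166 for 82 genes high at 2 against 400 µM, chosen without the 20 µM libraries. Members that did not pass between 2 and 20 µM stood above their 2 µM mean in TMM-scaled CPM, with shares of 1.07 for hrg-6, 1.74 for hrg-10, 2.50 for gst-22 and 3.99 for hrg-5. The TMM factor was 0.599 for 20 µM replicate 1 and 1.08 to 1.12 for the 2 µM libraries, which raises these shares. Those of hrg-6 and hrg-10 are thus above 1 only with this scaling. Material from the 2 µM libraries mixed in would give nearly all of the 82 genes about the same share of their 2 µM level. For hrg-7, hrg-3 and hrg-1 it would need a share of at least 0.114, taken from the highest 2 µM library. Set against their lowest 2 µM library, 20.7% of the 82 genes lay below 0.5 times that share, among them nep-8 with 0 counts, clec-45 with a share of 0.00203 and hrg-2 with 0.00412. This argues against such mixing as the whole source. Of the 82 genes 21.95% lay below a share of 0.05 of their 2 µM mean (quartiles 0.0652 and 0.301), and 39.0% with the level in the other 20 µM libraries subtracted. The first of these lies between the bounds set for either answer, so a small part from mixing stays open. Lower heme status of these worms at 20 µM may also give such levels and was not tested.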
